A study of Rattus norvegicus with 30 samples.

How the data were processed

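Total RNA of 30 rat (Sprague-Dawley) myelinating cultures was measured, 3 cultures in each of 10 groups, which were untreated cultures and cultures with FGF9, FGF1, FGF2 or BMP4 at 2 exposure times. Per the labels, RNA was labelled with a whole-transcript expression kit and hybridised to Affymetrix GeneChip arrays with 1 colour. The deposited value table holds 1 value per probe set and array, on a log2 scale as far as the values show, since the authors' table runs from 3.98 to 14.68 and the log base itself is inferred from that range and from the method named. Partek 6.6 and GCRMA, a background correction and quantile normalization with probe summarization, are named in the submitters' processing notes, with no settings. The array's genome build is not given in the sources used here, so no coordinates are printed. Array medians were 7.454 to 7.588 and lower quartiles 5.641 to 5.765. After quantile normalization, a change in total RNA content shared by most genes would not show. Compression of differences at low signal was tested for the neuronal list alone. No value was centred per probe set, as the range of signal shows.

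Samples were grouped by the labels' treatment and time. All 29214 probe sets were tested, control probe sets included if the table holds any, because no list of control probe sets was used here. Of these, 15310 had exactly 1 gene symbol in the platform annotation, 323 had several and were not named, and 13581 are unnamed here. Symbols were updated through the gene identifier for 15279 probe sets and the accession for 6, and 25 were kept as given; 2 changed. Of 14506 genes, 527 had more than 1 probe set; a named gene's value is that of its named probe set, and at most 4 genes in a comparison with controls had probe sets called both ways.

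Differences were tested on the deposited log2 values with limma 3.58.1 in R 4.3.3, by lmFit of 10 group means over all 30 arrays, contrasts and eBayes with default settings, two-sided, with Benjamini-Hochberg adjustment over all probe sets within each of 19 comparisons (8 of a factor with the controls of its time, 6 between FGFs, 1 of the controls at 10 days with those at 24 h, and 4 interactions of factor and time). The residual degrees of freedom were 20 (23.4 with the prior) and the median residual SD was 0.092. A probe set passed, or is called changed, at an adjusted p under 0.05.

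There were 19 gene lists: myelin, oligodendrocyte progenitor, astrocyte, reactive astrocyte, neuronal, microglial, endothelial, mesenchymal, Schwann cell, FGF and ERK response, BMP and SMAD target, cell cycle, cytokine, interferon-stimulated, protease, proteoglycan, cholesterol synthesis, stress response, and FGF receptor and ligand genes. They held 334 measured genes, 8 of them in more than 1 list, and many are expressed by several of the cell types. Each list was tested with limma's camera at a preset correlation between genes of 0.01, with 1 probe set per gene (that of the highest mean), against all genes with 1 symbol, and adjusted over the 19 lists of a comparison. In none of the 186 calls did median, mean and test differ in sign. Member calls come from the test of all probe sets; the counts adjusted over the list alone stand beside them.

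The text names, for each comparison, the 5 highest and 5 lowest log2 differences among probe sets that passed, had exactly 1 symbol not starting with LOC or RGD and, except for interactions, had all 3 arrays of one group beyond all 3 of the other, then up to 4 members of each list with the lowest p, and 18 genes fixed for every comparison (Mbp, Mag, Mog, Pdgfra, Gfap, Spry4, Dusp6, Etv4, Etv5, Id1, Id3, Smad7, Lif, Ccl2, Ccl7, Timp1 and Mki67, of which Mki67 is not analysed here, and 1 that is not reported here). Some genes the rule allows are left out. The groups, comparisons, tests, lists, naming rule and the alternatives were set before the data were examined, except where a test or alternative is said to have been chosen later.

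Alternatives were the replicate number as a block, leaving out low-signal probe sets, fitting only the arrays compared, a further quantile normalization, array weights, eBayes with trend and robust settings, leaving out each array in turn, and for lists an estimated correlation, the rotation test fry, the block and leaving out low-signal genes. Overlaps between factors were set beside unchanged groups simulated against the same controls (100 simulations) and beside the product of both counts divided by the number of probe sets. The fit was tested on simulated data of 29214 probe sets, 200 of them changed, far fewer than FGF9's calls. For FGF9 against controls at 24 h, 90%, 99.3% and 100% of probe sets changed 1.5-fold, 2-fold and 4-fold were recovered (150 each over 3 simulations), with a mean of 9 false calls, and for the FGF9 interaction 75.3%, 92.7% and 100%. At 1.25-fold, 50% and 24.7% were, and real rates may differ. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures, and statmod 1.5.0 was installed beside limma.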

Results

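Gene expression was measured in rat myelinating cultures, in which embryonic spinal cord cells are grown on a monolayer of astrocytes made from neurospheres of neonatal striatum, so that neurons, oligodendrocyte lineage cells, astrocytes and microglia can be present together. Recombinant human FGF9, FGF1, FGF2 or BMP4 was added at 18 days in vitro (DIV), or nothing was added, and RNA was taken at 24 h (19 DIV) and at 10 days (28 DIV). FGFs are growth factors that signal through receptor tyrosine kinases and ERK, and BMP4 signals through SMAD proteins. Each of the 10 groups held 3 arrays, 30 in all, and the 3 replicates of a group were independent cultures per the series design. The dose of each factor is not given in the sources used here. The median log2 signal of the arrays lay between 7.454 and 7.588. Correlations of log2 signal across probe sets were 0.996 to 0.9979 within groups (30 pairs of arrays) and 0.9703 to 0.9977 between groups (405 pairs), where probe sets are not independent replicates. The number of arrays limits the precision, and the median standard error of a 3 against 3 difference was 0.074 on the log2 scale.

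A value in brackets after a gene is the log2 difference between group means ± its standard error, with n = 3 arrays in each group, and every gene described as having risen or fallen passed an adjusted p of 0.05 over all 29214 probe sets. Medians of lists are of log2 differences. For the 5 genes named as highest or lowest in a comparison with controls, all 3 treated arrays lay beyond all 3 control arrays. Of the 87 gene lists called against controls, 82 had the list mean of all 3 treated arrays beyond that of all 3 control arrays, and the other 5 were the microglial and interferon-stimulated lists with BMP4 (at 24 h and 10 days, 2 of 3 arrays each) and, with FGF1 at 10 days, the mesenchymal and FGF and ERK response lists (2 of 3 arrays each) and the interferon-stimulated list (0 of 3 arrays).

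Within 24 h of FGF9, the largest rise was that of Ccl7 (log2 change 4.96 ± 0.13), a chemokine that attracts monocytes, whose probe set 10736702 read 12.21 ± 0.049 against 7.255 ± 0.25 (log2 signal, mean ± SD, n = 3 each), a 31-fold difference (adjusted p = 3.6e-19). The secreted metalloproteinase Adamts1 (4.31 ± 0.16), the keratin Krt18 (4.21 ± 0.13), the membrane glycoprotein Cd93 (4.13 ± 0.15) and the cytokine Clcf1 (3.83 ± 0.098) followed. The largest falls were those of Bbox1 (-3.35 ± 0.18), which makes carnitine, Aox1 (-3.21 ± 0.11), an aldehyde oxidase, Spata18 (-3.15 ± 0.15), Nt5c1a (-3.11 ± 0.099), a nucleotidase, and Hgf (-3.00 ± 0.074), hepatocyte growth factor. Feedback inhibitors and targets of FGF and ERK signalling rose together. Among them, 18 of 19 rose and 0 fell (18 and 0 adjusted over the list alone, median 1.5, camera adjusted p = 8e-16), including Spry4 (2.89 ± 0.085), Dusp6 (2.33 ± 0.082), Etv5 (1.52 ± 0.079) and Ccnd1 (2.93 ± 0.074), a G1 cyclin.

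Astrocyte and oligodendrocyte lineage genes fell with FGF9 at 24 h. Of the astrocyte genes, 15 of 16 fell and 0 rose (15 and 0 adjusted over the list alone, median -0.63, camera adjusted p = 1.3e-11). Examples are Aqp4 (-1.07 ± 0.043), the water channel of astrocyte endfeet, Aldh1l1 (-0.89 ± 0.047) and Slc1a2 (-0.76 ± 0.048), a glutamate transporter. Among myelin genes, 17 of 26 fell and 1 rose (17 and 1 adjusted over the list alone, median -0.69, camera adjusted p = 9.4e-07, adjusted p = 0.14 with an estimated correlation). Members include Mal (-2.50 ± 0.12), Ermn (-1.96 ± 0.098), Mbp (-0.79 ± 0.08) and Mog (-0.76 ± 0.085). For oligodendrocyte progenitor genes, 11 of 13 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.50, camera adjusted p = 3.6e-05, adjusted p = 0.053 with an estimated correlation). These include Gpr17 (-1.76 ± 0.09) and Pdgfra (-0.48 ± 0.058). Cell cycle genes went up. Of these, 19 of 21 rose and 1 fell (19 and 1 adjusted over the list alone, median 1.01, camera adjusted p = 1.2e-08, adjusted p = 0.2 with an estimated correlation). Among them are Mcm5 (1.91 ± 0.14) and Cdk1 (1.43 ± 0.12). In the list of BMP and SMAD targets, 9 of 17 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.38, camera adjusted p = 0.011, adjusted p = 0.14 with an estimated correlation). Members such as Id3 (-2.14 ± 0.14) and Id4 (-1.37 ± 0.06) were lower and Smad9 (1.37 ± 0.071) higher. Id1 (0.20 ± 0.1) and Smad7 (-0.18 ± 0.098) did not pass (Id1 passed without control replicate 3, limma adjusted p = 0.038).

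Further lists were called with FGF9 at 24 h. Of the neuronal genes, 12 of 23 fell and 1 rose (17 and 1 adjusted over the list alone, median -0.22, camera adjusted p = 0.0052, adjusted p = 0.44 with an estimated correlation). Of the interferon-stimulated genes, 12 of 17 fell and 1 rose (12 and 2 adjusted over the list alone, median -0.77, camera adjusted p = 0.0014, adjusted p = 0.42 with an estimated correlation). Examples are Rsad2 (-2.64 ± 0.36) and Stat2 (-1.08 ± 0.094). Among genes reported as raised in reactive astrocytes, 11 of 24 rose and 5 fell (12 and 5 adjusted over the list alone, median 0.22, camera adjusted p = 0.0086, adjusted p = 0.42 with an estimated correlation, adjusted p = 0.07 without low-signal genes). Members include Socs3 (2.42 ± 0.09), Nes (2.37 ± 0.073) and Timp1 (1.34 ± 0.063), whereas Gfap (-0.77 ± 0.046), the astrocyte intermediate filament, fell. Protease genes included Plau (3.18 ± 0.095) and Plaur (2.63 ± 0.082), urokinase and its receptor, and 11 of 20 rose and 4 fell (11 and 4 adjusted over the list alone, median 0.40, camera adjusted p = 0.0056, adjusted p = 0.14 with an estimated correlation). The FGF receptors and ligands were also tested, and 9 of 15 fell and 1 rose (10 and 1 adjusted over the list alone, median -0.18, camera adjusted p = 0.0099, adjusted p = 0.14 with an estimated correlation). Members such as Fgfr2 (-0.39 ± 0.038) and Fgfr3 (-0.42 ± 0.052) were lower and Fgf2 (0.64 ± 0.067) higher. The cytokine list was not called (camera adjusted p = 0.36), although Ccl2 (2.31 ± 0.086), Lif (2.51 ± 0.18) and Il11 (3.21 ± 0.14) rose and Il33 (-2.31 ± 0.12) fell. In total, 10439 probe sets passed in limma, 5216 higher and 5223 lower, of which 1296 and 1172 by 1.5-fold or more. Of the 19 lists, 13 were called, and the astrocyte and FGF and ERK response lists held with an estimated correlation.

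FGF1 gave at 24 h its largest rises in Lrrc15 (log2 change 3.52 ± 0.098), a leucine-rich repeat membrane protein (probe set 10751793, log2 signal 10.96 ± 0.029 SD against 7.44 ± 0.23 SD), in Spon2 (3.35 ± 0.12), an extracellular matrix protein, and in Ccl7 (3.16 ± 0.13). Tbxas1 (2.78 ± 0.093), thromboxane synthase, and Gldn (2.76 ± 0.18), gliomedin, came next. The largest falls were in Aox1 (-2.49 ± 0.11), Cyp4f4 (-1.97 ± 0.063), Cldn10 (-1.92 ± 0.11), a claudin, Car3 (-1.90 ± 0.13), a carbonic anhydrase, and Papss2 (-1.89 ± 0.14), which makes the sulphate donor for proteoglycans. Of the FGF and ERK response genes, 16 of 19 rose and 0 fell (17 and 0 adjusted over the list alone, median 0.65, camera adjusted p = 2.3e-12). These include Ccnd1 (1.72 ± 0.074), Etv5 (1.24 ± 0.079), Spry4 (0.67 ± 0.085) and Dusp6 (0.65 ± 0.082). Astrocyte genes fell. Of these, 13 of 16 fell and 0 rose (14 and 0 adjusted over the list alone, median -0.38, camera adjusted p = 8.8e-11). Among them are Mfge8 (-0.73 ± 0.064) and S100b (-0.63 ± 0.056).

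Reactive astrocyte genes rose with FGF1 at 24 h. Of these, 14 of 24 rose and 2 fell (14 and 3 adjusted over the list alone, median 0.51, camera adjusted p = 2.8e-07, adjusted p = 0.13 with an estimated correlation). Examples are Socs3 (2.70 ± 0.09) and Nes (1.86 ± 0.073). Cell cycle genes did likewise, and 18 of 21 rose and 1 fell (18 and 1 adjusted over the list alone, median 0.71, camera adjusted p = 1.4e-09, adjusted p = 0.22 with an estimated correlation). An example is Mcm5 (1.54 ± 0.14). For progenitor genes of the oligodendrocyte lineage, 10 of 13 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.36, camera adjusted p = 7.5e-05, adjusted p = 0.067 with an estimated correlation). Members such as Tnr (-0.88 ± 0.076) and Gpr17 (-0.85 ± 0.09) were lower but Olig1 (0.74 ± 0.044), a lineage transcription factor, higher. For myelin genes, 14 of 26 fell and 2 rose (14 and 2 adjusted over the list alone, median -0.21, camera adjusted p = 0.00025, adjusted p = 0.25 with an estimated correlation). Members include Mal (-1.54 ± 0.12) and Mbp (-0.35 ± 0.08). Lif, induced by the other FGFs, stood at 0.086 ± 0.18 with FGF1 and did not pass. In total, 6974 probe sets passed in limma, 3742 higher and 3232 lower, of which 580 and 475 by 1.5-fold or more. Of the lists, 10 were called and the astrocyte and FGF and ERK response lists held with an estimated correlation.

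With FGF2 at 24 h, Ccl7 (log2 change 4.99 ± 0.13), Cd93 (4.72 ± 0.15), Adamts1 (4.25 ± 0.16), Krt18 (4.15 ± 0.13) and Spon2 (4.15 ± 0.12) rose most, with Cd93 (probe set 10850530) at 10.65 ± 0.07 against 5.93 ± 0.13 (log2 signal, mean ± SD, n = 3 each). The lowest were Aox1 (-3.27 ± 0.11), Hgf (-2.93 ± 0.074), Car3 (-2.76 ± 0.13), Cyp4f4 (-2.74 ± 0.063) and Capsl (-2.67 ± 0.17). Lif (3.71 ± 0.18), leukaemia inhibitory factor, Il11 (3.91 ± 0.14) and Ccl2 (2.20 ± 0.086) rose within the cytokine list, which was not called as a whole (camera adjusted p = 0.17). Proteases rose. Of these, 13 of 20 rose and 4 fell (13 and 4 adjusted over the list alone, median 0.54, camera adjusted p = 2e-04). These include Plau (3.51 ± 0.095), Plaur (3.01 ± 0.082) and Mmp13 (2.61 ± 0.091), a collagenase. For the FGF and ERK response, 18 of 19 rose and 0 fell (18 and 0 adjusted over the list alone, median 1.61, camera adjusted p = 5.4e-15). Among them are Spry4 (3.09 ± 0.085), Dusp6 (2.46 ± 0.082) and Phlda1 (3.09 ± 0.088).

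Oligodendrocyte lineage and astrocyte lists fell with FGF2 at 24 h, while reactive astrocyte and cell cycle lists rose. Oligodendrocyte progenitor genes showed Gpr17 (-2.21 ± 0.09), Pdgfra (-0.91 ± 0.058) and Cspg5 (-1.01 ± 0.053), and 11 of 13 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.63, camera adjusted p = 8.5e-07). Astrocyte genes included Aldh1l1 (-1.03 ± 0.047), Aqp4 (-0.98 ± 0.043) and Slc1a2 (-0.87 ± 0.048), and 15 of 16 fell and 0 rose (15 and 0 adjusted over the list alone, median -0.75, camera adjusted p = 1.2e-11). Myelin genes included Mal (-2.22 ± 0.12), Fa2h (-1.67 ± 0.1), a fatty acid hydroxylase of myelin lipids, and Mbp (-0.62 ± 0.08), and 18 of 26 fell and 1 rose (18 and 1 adjusted over the list alone, median -0.59, camera adjusted p = 1.8e-06, adjusted p = 0.17 with an estimated correlation). Of the neuronal genes, 16 of 23 fell and 1 rose (16 and 1 adjusted over the list alone, median -0.24, camera adjusted p = 0.012, adjusted p = 0.52 with an estimated correlation). Among reactive astrocyte genes, 13 of 24 rose and 4 fell (15 and 5 adjusted over the list alone, median 0.32, camera adjusted p = 0.0034, adjusted p = 0.31 with an estimated correlation). An example is Socs3 (2.53 ± 0.09). Among cell cycle genes, 19 of 21 rose and 1 fell (19 and 1 adjusted over the list alone, median 0.85, camera adjusted p = 1.7e-06, adjusted p = 0.26 with an estimated correlation). An example is Mcm5 (1.91 ± 0.14). In total, 11223 probe sets passed in limma, 5601 higher and 5622 lower, of which 1424 and 1431 by 1.5-fold or more. Of the lists, 12 were called, and the oligodendrocyte progenitor, astrocyte, FGF and ERK response and protease lists held with an estimated correlation.

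BMP4 at 24 h raised inhibitors of its own pathway. Nog (log2 change 3.46 ± 0.058), noggin (probe set 10746172), read 11.74 ± 0.056 against 8.276 ± 0.085 (log2 signal, mean ± SD, n = 3 each), 11-fold higher (adjusted p = 1.2e-22), and Smad6 (3.34 ± 0.092), an inhibitory SMAD, was next. Papss2 (2.08 ± 0.14), which makes a sulphate donor, and Atoh8 (2.01 ± 0.1), a transcription factor, also rose. Aspn (3.07 ± 0.81), a small matrix proteoglycan, passed with a wide spread, but not without BMP4 replicate 1 or 2 or control replicate 2 or 3 (limma adjusted p = 0.086, 0.079, 0.051 and 0.054). The largest falls were those of Tmem255b (-2.98 ± 0.11), Gpr17 (-2.45 ± 0.09), a receptor of committed oligodendrocyte progenitors, Gpr20 (-2.30 ± 0.12), Cspg4 (-2.21 ± 0.082), the NG2 proteoglycan, and Pmp2 (-1.44 ± 0.32), a lipid-binding protein of myelin. Of the BMP and SMAD target genes, 12 of 17 rose and 1 fell (12 and 1 adjusted over the list alone, median 1.05, camera adjusted p = 5.1e-24). Examples are Bambi (1.72 ± 0.082), Smad7 (1.76 ± 0.098), Id1 (1.29 ± 0.1) and Id3 (1.28 ± 0.14). Oligodendrocyte progenitor genes fell, and 8 of 13 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.48, camera adjusted p = 1.6e-12). Members include Pdgfra (-1.14 ± 0.058) and Olig1 (-0.70 ± 0.044).

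Enzymes of cholesterol synthesis rose with BMP4 at 24 h by small amounts. Of these, 12 of 20 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 8.6e-11). These include Acat2 (0.47 ± 0.043) and Dhcr7 (0.38 ± 0.056). Cell cycle genes fell, and 12 of 21 fell and 0 rose (16 and 0 adjusted over the list alone, median -0.40, camera adjusted p = 1.5e-10, adjusted p = 0.22 with an estimated correlation). Among them are Rrm2 (-0.92 ± 0.13) and Top2a (-0.71 ± 0.13). For myelin genes, 7 of 26 fell and 1 rose (9 and 3 adjusted over the list alone, median -0.10, camera adjusted p = 0.00048, adjusted p = 0.39 with an estimated correlation). Examples are Bcas1 (-1.41 ± 0.076) and Enpp6 (-1.31 ± 0.16), genes of newly formed oligodendrocytes. Mbp (-0.043 ± 0.08), Mag (-0.0027 ± 0.082) and Mog (-0.26 ± 0.085) did not pass. The chemokines Ccl2 (-0.99 ± 0.086) and Ccl7 (-0.88 ± 0.13) fell. In total, 2066 probe sets passed in limma, 1016 higher and 1050 lower, of which 182 and 173 by 1.5-fold or more, and with only the 6 arrays compared in the fit the count was 1321. Of the lists, 10 were called, and the oligodendrocyte progenitor, BMP and SMAD target and cholesterol synthesis lists held with an estimated correlation.

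**Figure D1:**
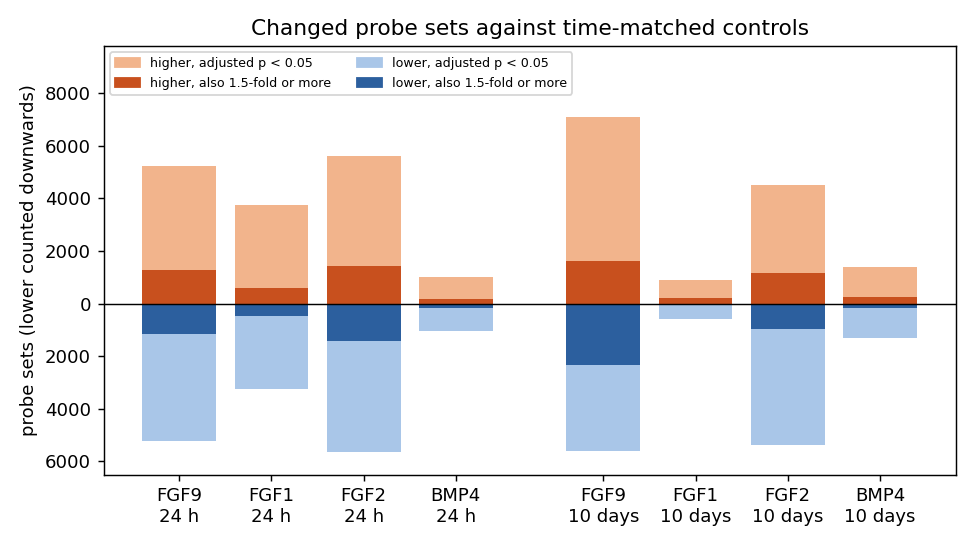
Number of probe sets higher (upwards) and lower (downwards) than in the time-matched controls for each factor and time, out of 29214 tested, with 3 arrays per group. Pale bars count adjusted p under 0.05 and dark bars those that also changed by 1.5-fold or more; the FGF9 bars at 10 days reach 7087 higher and 5609 lower, and the FGF1 bars at 10 days 912 and 573.

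After 10 days with FGF9, Sectm1b (log2 change 4.95 ± 0.12) rose most (probe set 10749762, log2 signal 11.48 ± 0.18 SD against 6.522 ± 0.038 SD). Next were Dio2 (4.47 ± 0.21), the deiodinase that activates thyroid hormone, Car9 (4.21 ± 0.27), a carbonic anhydrase, Anpep (4.16 ± 0.21), an aminopeptidase, and the imprinted RNA H19 (3.99 ± 0.68), whose cultures varied widely. The lowest were Spata18 (-3.14 ± 0.15), Bbox1 (-3.03 ± 0.18), Hydin (-2.93 ± 0.14), a protein of motile cilia, Liat1 (-2.62 ± 0.17) and Nefh (-2.61 ± 0.13), a neurofilament. Neuronal genes fell as a group. Of these, 22 of 23 fell and 0 rose (22 and 0 adjusted over the list alone, median -1.14, camera adjusted p = 1.3e-16, adjusted p = 0.1 with an estimated correlation). Members include Scn2a (-1.73 ± 0.076), a sodium channel, Rbfox3 (-1.48 ± 0.072), Syn1 (-1.33 ± 0.057), a synaptic vesicle protein, and Syt1 (-1.09 ± 0.052), a calcium sensor of vesicle release.

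The FGF and ERK response genes stayed raised at 10 days of FGF9. Of these, 19 of 19 rose and 0 fell (19 and 0 adjusted over the list alone, median 1.15, camera adjusted p = 2.2e-11). These include Etv4 (2.93 ± 0.094), Dusp6 (2.70 ± 0.082), Spry4 (2.48 ± 0.085) and Ccnd1 (2.33 ± 0.074). Cell cycle genes were raised too, and 20 of 21 rose and 1 fell (20 and 1 adjusted over the list alone, median 1.53, camera adjusted p = 5.3e-09, adjusted p = 0.21 with an estimated correlation). Among them are Rrm2 (2.28 ± 0.13) and Cdk1 (2.15 ± 0.12). Astrocyte genes, lower at 24 h, were now higher, and 13 of 16 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.35, camera adjusted p = 0.0011, adjusted p = 0.21 with an estimated correlation). Examples are Fgfr3 (1.26 ± 0.052) and Aldh1l1 (0.64 ± 0.047). Myelin genes went both ways. Of these, 15 of 26 fell and 6 rose (16 and 7 adjusted over the list alone, median -0.47, camera adjusted p = 0.0034, adjusted p = 0.46 with an estimated correlation). Members such as Nipal4 (-1.53 ± 0.1), Mobp (-1.42 ± 0.1), Mog (-0.96 ± 0.085), Mag (-0.72 ± 0.082) and Mbp (-0.59 ± 0.08) were lower but Aspa (1.03 ± 0.069), which breaks down N-acetylaspartate, higher. The oligodendrocyte progenitor list was not called (camera adjusted p = 0.12), with Olig1 (1.05 ± 0.044) and Cspg4 (1.00 ± 0.082) among 9 of 13 members that rose.

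With FGF9 at 10 days, of proteoglycans and their enzymes 14 of 18 rose and 2 fell (14 and 2 adjusted over the list alone, median 0.60, camera adjusted p = 0.00036, adjusted p = 0.14 with an estimated correlation). Members include Xylt1 (1.35 ± 0.077) and Chst11 (1.07 ± 0.048), which build and sulphate chondroitin chains, and Hapln1 (-1.64 ± 0.083), a link protein, lower. For mesenchymal genes, 10 of 16 rose and 1 fell (12 and 1 adjusted over the list alone, median 1.01, camera adjusted p = 0.022, adjusted p = 0.48 with an estimated correlation, adjusted p = 0.31 without low-signal genes). These include Postn (3.44 ± 0.43) and Mgp (3.35 ± 0.28). Reactive astrocyte genes included Lcn2 (3.44 ± 0.2), lipocalin, and Nes (1.76 ± 0.073), and 15 of 24 rose and 4 fell (16 and 4 adjusted over the list alone, median 0.55, camera adjusted p = 0.0011, adjusted p = 0.3 with an estimated correlation). Interferon-stimulated genes fell. Of these, 13 of 17 fell and 1 rose (14 and 1 adjusted over the list alone, median -0.65, camera adjusted p = 0.0014, adjusted p = 0.47 with an estimated correlation). Among them are Rsad2 (-2.41 ± 0.36) and Isg15 (-1.86 ± 0.23). Microglial genes included Cd68 (1.27 ± 0.11) and Trem2 (0.84 ± 0.16), and 15 of 19 rose and 0 fell (15 and 0 adjusted over the list alone, median 0.37, camera adjusted p = 0.028, adjusted p = 0.48 with an estimated correlation, adjusted p = 0.064 without low-signal genes). In total, 12696 probe sets passed in limma, 7087 higher and 5609 lower, of which 1619 and 2315 by 1.5-fold or more. The median log2 difference of all probe sets was 0.051, and 66.2% of the changed probe sets of low signal were higher, against 52.4% of those of high signal. Of the lists, 11 were called, and only the FGF and ERK response list held with an estimated correlation.

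FGF1 at 10 days gave smaller changes. The largest rises were in Cd74 (log2 change 1.93 ± 0.35), the invariant chain of antigen presentation (probe set 10802013, log2 signal 10.68 ± 0.18 SD against 8.749 ± 0.35 SD), the calcium-binding proteins S100a4 (1.74 ± 0.14) and S100a6 (1.55 ± 0.17), the protease inhibitor Serpina3n (1.65 ± 0.17) and the apelin receptor Aplnr (1.59 ± 0.17). The largest falls were in Slc7a3 (-2.20 ± 0.15), a transporter of cationic amino acids, Trib3 (-2.0 ± 0.13) and Atf5 (-2.0 ± 0.13), which are induced by amino acid shortage and other stress, Sucnr1 (-1.35 ± 0.12), a succinate receptor, and Mthfd2 (-1.34 ± 0.096), a mitochondrial folate enzyme. Microglial genes rose. Of these, 18 of 19 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.76, camera adjusted p = 6.9e-29). Examples are Mrc1 (1.06 ± 0.1), Cd68 (0.97 ± 0.11) and C1qa (0.92 ± 0.094), a complement component. For reactive astrocyte genes, 11 of 24 rose and 0 fell (17 and 1 adjusted over the list alone, median 0.35, camera adjusted p = 1.2e-12). Members include Hspb1 (0.88 ± 0.11) and Cp (0.81 ± 0.084), ceruloplasmin. Genes of the stress response fell, and 6 of 14 fell and 0 rose (6 and 0 adjusted over the list alone, median -0.032, camera adjusted p = 2.1e-05). Those that fell include Chac1 (-0.86 ± 0.075) and Atf4 (-0.77 ± 0.067).

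Myelin genes were not called with FGF1 at 10 days (camera adjusted p = 0.41), with Mbp (-0.031 ± 0.08), Mag (-0.012 ± 0.082) and Mog (0.014 ± 0.085), while Tf (1.01 ± 0.15), transferrin, rose. For oligodendrocyte progenitor genes, 6 of 13 fell and 1 rose (7 and 1 adjusted over the list alone, median -0.15, camera adjusted p = 2.6e-05). Among them are Gpr17 (-0.56 ± 0.09) and Cspg4 (-0.47 ± 0.082). Among the cholesterol synthesis genes, 10 of 20 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.16, camera adjusted p = 5.8e-08). An example is Idi1 (0.43 ± 0.057). For BMP and SMAD targets, 5 of 17 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.12, camera adjusted p = 2.6e-05). Examples are Id1 (0.58 ± 0.1) and Id3 (0.67 ± 0.14). Endothelial genes had 1 member pass, Esam (0.86 ± 0.12), a junction protein, and 1 of 10 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.062, camera adjusted p = 0.047, adjusted p = 0.31 with an estimated correlation, adjusted p = 0.18 without low-signal genes). In the cytokine list, 4 of 25 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.10, camera adjusted p = 0.0062, adjusted p = 0.27 with an estimated correlation). Members include Ccl7 (0.78 ± 0.13) and Ccl2 (0.51 ± 0.086). Of the FGF and ERK response genes, 2 of 19 fell and 2 rose (5 and 2 adjusted over the list alone, median -0.18, camera adjusted p = 0.017, adjusted p = 0.31 with an estimated correlation, adjusted p = 0.066 without low-signal genes). Dusp6 (0.46 ± 0.082) rose, Spry2 (-0.43 ± 0.065) fell and Spry4 (-0.14 ± 0.085) did not pass.

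For FGF1 at 10 days, 1485 probe sets passed in limma, 912 higher and 573 lower, of which 224 and 47 by 1.5-fold or more. The count was 938 with only the 6 arrays compared in the fit, 853 without control replicate 3, 943 without FGF1 replicate 2 and 889 without FGF1 replicate 3. Of the lists, 13 were called, and the oligodendrocyte progenitor, reactive astrocyte, microglial, BMP and SMAD target, cholesterol synthesis and stress response lists held with an estimated correlation.

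After 10 days of FGF2, Sectm1b (log2 change 4.58 ± 0.12) (probe set 10749762) again rose most, at 11.1 ± 0.15 against 6.522 ± 0.038 (log2 signal, mean ± SD, n = 3 each). Next were H19 (4.35 ± 0.68), Cyp4b1 (4.14 ± 0.18), a cytochrome P450, Moxd1 (3.74 ± 0.18) and Ptx3 (3.47 ± 0.098), a pentraxin of innate immunity. Sucnr1 (-2.30 ± 0.12), Atf5 (-2.09 ± 0.13), Trib3 (-2.0 ± 0.13), Ermn (-2.0 ± 0.098), a cytoskeletal protein of myelinating oligodendrocytes, and Scd (-1.82 ± 0.082), a fatty acid desaturase, fell most. Reactive astrocyte genes rose broadly. Of these, 22 of 24 rose and 0 fell (22 and 0 adjusted over the list alone, median 1.10, camera adjusted p = 7.1e-16). These include Socs3 (2.58 ± 0.09), Aspg (1.88 ± 0.079) and Timp1 (1.46 ± 0.063). Gfap (0.14 ± 0.046) passed, but not after a further quantile normalization (limma adjusted p = 0.13) or without any 1 of 4 arrays (adjusted p = 0.053 to 0.11). Microglial genes rose, and 18 of 19 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.88, camera adjusted p = 2.2e-10, adjusted p = 0.18 with an estimated correlation). Among them are Cd163 (2.11 ± 0.14), a scavenger receptor of macrophages, Mrc1 (1.54 ± 0.1) and Cd68 (1.37 ± 0.11).

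Neuronal genes fell with FGF2 at 10 days. Of these, 20 of 23 fell and 1 rose (20 and 2 adjusted over the list alone, median -0.51, camera adjusted p = 9.1e-09, adjusted p = 0.27 with an estimated correlation). Examples are Nefm (-1.17 ± 0.11), a neurofilament, Dcx (-1.04 ± 0.08), of young neurons, and Syn1 (-0.61 ± 0.057). For myelin genes, 16 of 26 fell and 4 rose (16 and 4 adjusted over the list alone, median -0.30, camera adjusted p = 0.0016, adjusted p = 0.36 with an estimated correlation, adjusted p = 0.089 without low-signal genes). Members such as Nipal4 (-1.24 ± 0.1), Mog (-0.97 ± 0.085), Mbp (-0.52 ± 0.08) and Mag (-0.49 ± 0.082) were lower and Tf (2.25 ± 0.15) higher. Oligodendrocyte progenitor genes included Pdgfra (-0.75 ± 0.058) and Cspg4 (-0.64 ± 0.082), and 8 of 13 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.30, camera adjusted p = 0.01, adjusted p = 0.27 with an estimated correlation, adjusted p = 0.14 without low-signal genes). Of the FGF and ERK response genes, 10 of 19 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 0.0081, adjusted p = 0.33 with an estimated correlation). Members include Fos (1.03 ± 0.072) and Dusp6 (1.00 ± 0.082). Etv4 (0.082 ± 0.094) and Etv5 (0.10 ± 0.079) did not pass. Cell cycle genes were not called (camera adjusted p = 0.43), with Mcm2 (0.46 ± 0.074) higher and Top2a (-0.47 ± 0.13) lower, the latter not passing without FGF2 replicate 2 (limma adjusted p = 0.055). In total, 9873 probe sets passed in limma, 4516 higher and 5357 lower, of which 1157 and 954 by 1.5-fold or more. Of the lists, 9 were called, and only the reactive astrocyte list held with an estimated correlation.

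BMP4 at 10 days raised Aplnr (log2 change 3.96 ± 0.17), the apelin receptor, most (probe set 10837424, log2 signal 9.809 ± 0.31 SD against 5.847 ± 0.034 SD). Pclaf (1.91 ± 0.19) and Ect2 (1.82 ± 0.14), of DNA replication and cytokinesis, and Snai2 (1.87 ± 0.38), a transcription factor, also rose. Slc7a3 (-2.27 ± 0.15), Casp4 (-2.20 ± 0.17), an inflammatory caspase, Trib3 (-2.15 ± 0.13), Atf5 (-2.12 ± 0.13) and Erbb3 (-1.71 ± 0.13), a neuregulin receptor, fell most. Aspn (2.87 ± 0.81), next after Aplnr among the genes named, passed, but not without BMP4 replicate 1 (1.84) or control replicate 2 (2.54) or 3 (2.41), where limma gave an adjusted p = 0.17, 0.11 and 0.12. Myelin genes fell together. Of these, 23 of 26 fell and 1 rose (24 and 2 adjusted over the list alone, median -0.76, camera adjusted p = 1.7e-37). These include Mag (-1.51 ± 0.082), Nipal4 (-1.5 ± 0.1), Mog (-1.43 ± 0.085) and Mbp (-0.97 ± 0.08). Cell cycle genes rose. Of these, 21 of 21 rose and 0 fell (21 and 0 adjusted over the list alone, median 1.19, camera adjusted p = 5e-33). Among them are Top2a (1.71 ± 0.13), Rrm2 (1.71 ± 0.13) and Plk1 (1.53 ± 0.12).

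Oligodendrocyte progenitor genes were also lower with BMP4 at 10 days, and 8 of 13 fell and 1 rose (11 and 2 adjusted over the list alone, median -0.22, camera adjusted p = 1.7e-08). Examples are Cspg4 (-1.49 ± 0.082), Gpr17 (-1.45 ± 0.09) and Pdgfra (-0.52 ± 0.058). For BMP and SMAD targets, 10 of 17 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.38, camera adjusted p = 3.1e-13). Members include Smad6 (0.99 ± 0.092), Id3 (0.93 ± 0.14) and Nog (0.73 ± 0.058). Smad7 (0.15 ± 0.098) did not pass. Stress response genes fell. Of these, 7 of 14 fell and 0 rose (8 and 0 adjusted over the list alone, median -0.23, camera adjusted p = 5.1e-10). These include Atf3 (-1.05 ± 0.091) and Chac1 (-0.96 ± 0.075). For reactive astrocyte genes, 10 of 24 fell and 1 rose (10 and 2 adjusted over the list alone, median -0.22, camera adjusted p = 5.6e-06, adjusted p = 0.12 with an estimated correlation). Among them are Lcn2 (-1.37 ± 0.2), Osmr (-1.03 ± 0.072) and Timp1 (-0.65 ± 0.063). Gfap (-0.091 ± 0.046) did not pass. In the Schwann cell list, 2 of 9 fell and 0 rose (3 and 0 adjusted over the list alone, median -0.10, camera adjusted p = 0.0039, adjusted p = 0.091 with an estimated correlation). An example is Sox10 (-0.39 ± 0.073), which oligodendrocytes also express. In total, 2694 probe sets passed in limma, 1386 higher and 1308 lower, of which 250 and 179 by 1.5-fold or more, and with only the 6 arrays compared in the fit the count was 1319. Of the lists, 9 were called, and the myelin, oligodendrocyte progenitor, BMP and SMAD target, cell cycle and stress response lists held with an estimated correlation.

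**Figure D2:**
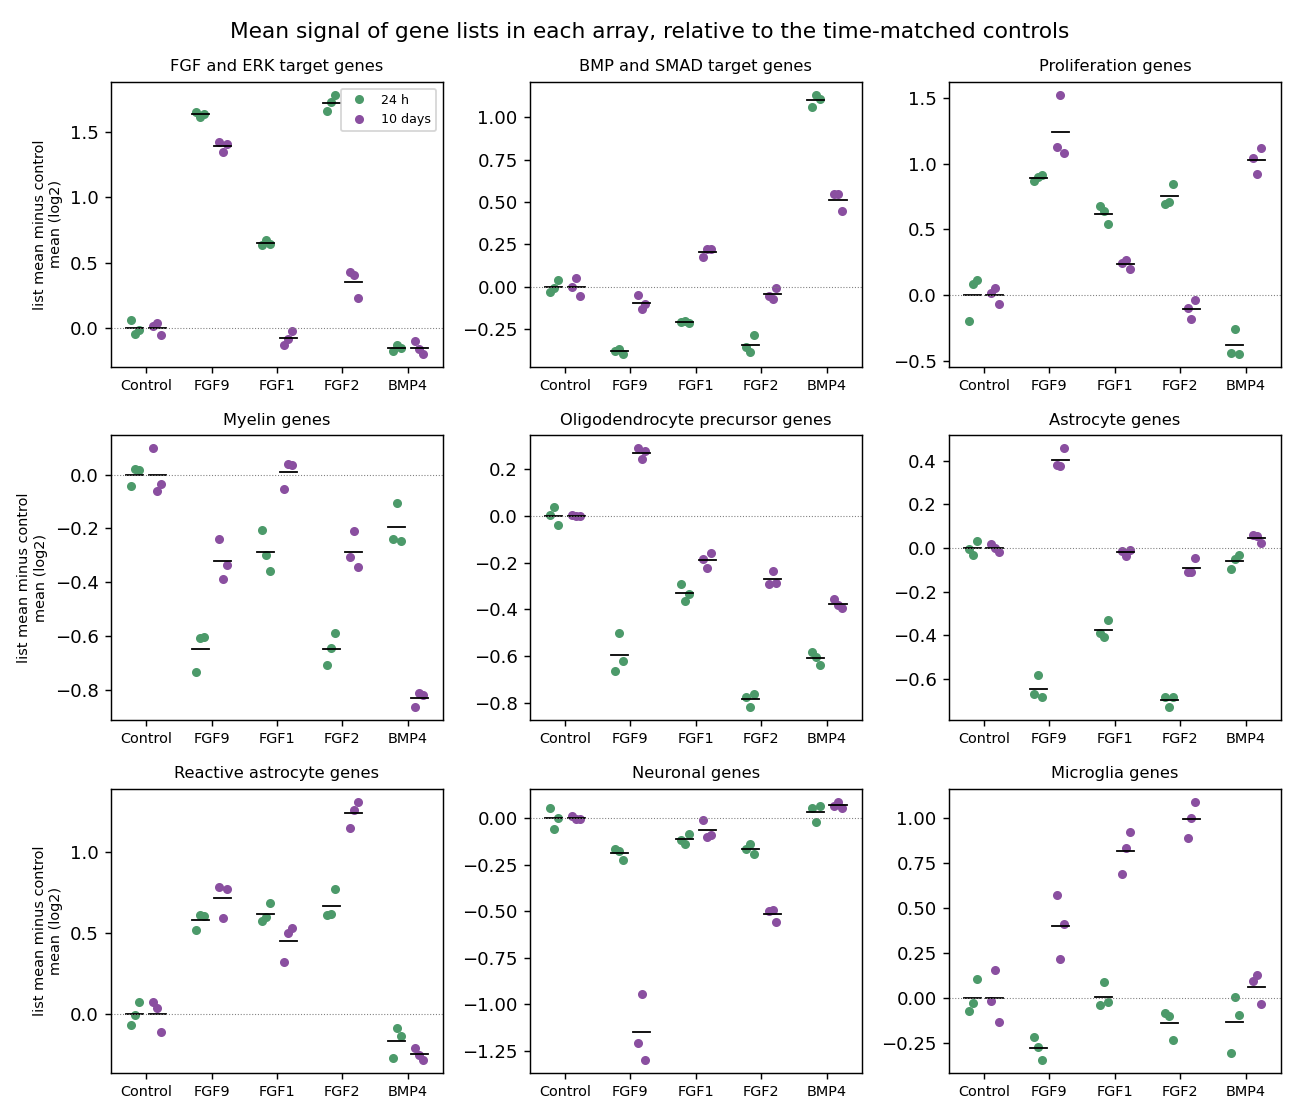
Mean log2 signal of 9 gene lists in each array minus the mean of the 3 control arrays of the same time, for controls and each factor at 24 h (green) and 10 days (purple). Points are single arrays and black bars group means; with FGF9 at 10 days the neuronal list lies below the controls, where its median log2 difference was -1.14.

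Untreated cultures also changed between the collection times, from 19 to 28 DIV. Mog (log2 change 1.99 ± 0.085), an outer myelin protein, rose most (probe set 10827673, log2 signal 10.77 ± 0.12 SD against 8.787 ± 0.055 SD). Next were the sodium channel subunit Scn4b (1.84 ± 0.11), Trib3 (1.82 ± 0.13), Cldn11 (1.74 ± 0.12), the claudin of myelin, and Erbb3 (1.58 ± 0.13). Lyve1 (-2.29 ± 0.15), a hyaluronan receptor, Nmu (-1.52 ± 0.12), a neuropeptide, Dlx5 (-1.47 ± 0.12), Cfp (-1.40 ± 0.14), properdin, and Prokr2 (-1.29 ± 0.11) fell most. Myelin genes rose. Of these, 23 of 26 rose and 0 fell (23 and 1 adjusted over the list alone, median 0.85, camera adjusted p = 4.9e-29). Examples are Mobp (1.53 ± 0.1), Mag (1.5 ± 0.082) and Mbp (1.04 ± 0.08). Stress response genes rose too, and 7 of 14 rose and 3 fell (8 and 3 adjusted over the list alone, median 0.21, camera adjusted p = 0.0037, adjusted p = 0.073 without low-signal genes). Members include Atf3 (1.33 ± 0.091) and Chac1 (0.67 ± 0.075). Cell cycle genes fell, and 18 of 21 fell and 0 rose (18 and 0 adjusted over the list alone, median -0.70, camera adjusted p = 5.4e-13, adjusted p = 0.2 with an estimated correlation). These include Top2a (-1.07 ± 0.13) and Aurkb (-1.01 ± 0.097). Microglial genes included Cd163 (-0.91 ± 0.14), and 9 of 19 fell and 0 rose (9 and 0 adjusted over the list alone, median -0.28, camera adjusted p = 0.0012, adjusted p = 0.5 with an estimated correlation). In total, 5138 probe sets passed in limma, 2351 higher at 10 days and 2787 lower, of which 205 and 298 by 1.5-fold or more. Of the lists, 8 were called, and the myelin and stress response lists held with an estimated correlation.

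**Figure D3:**
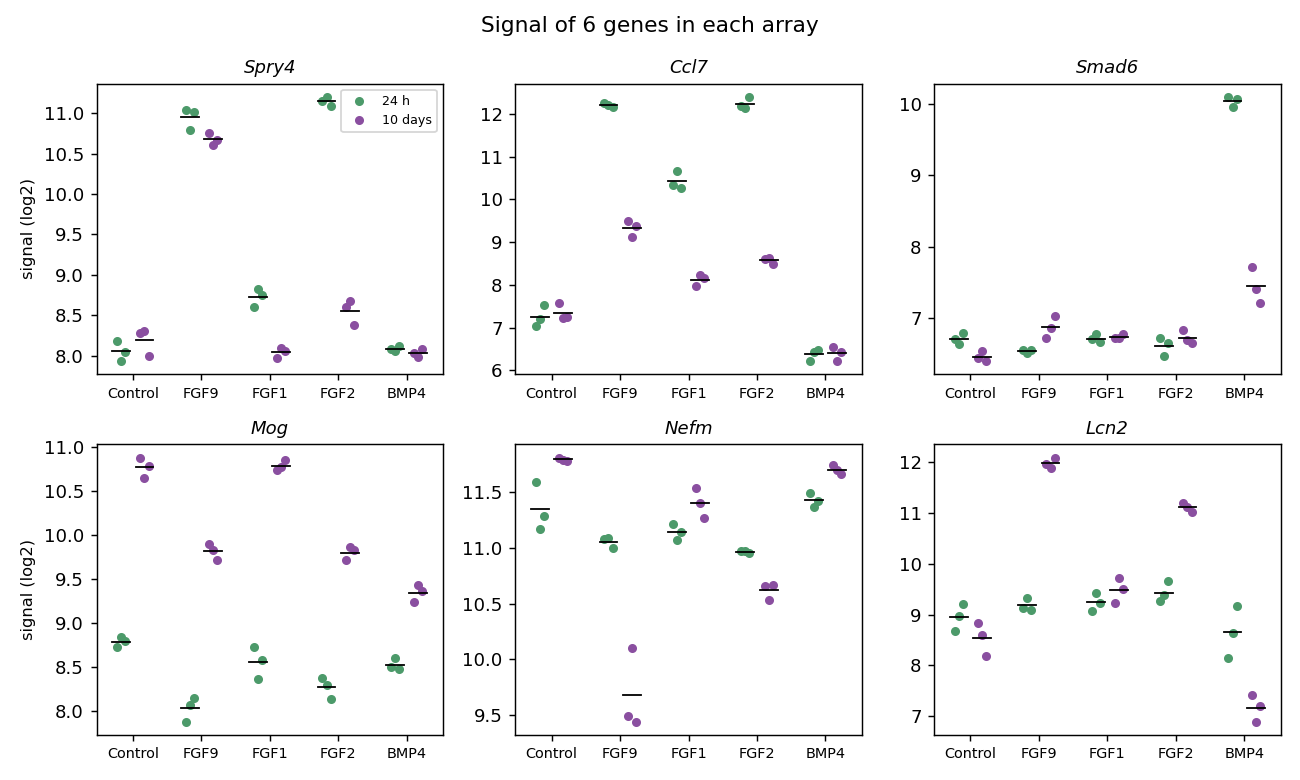
Log2 signal of Spry4, Ccl7, Smad6, Mog, Nefm and Lcn2 in each of the 30 arrays, by factor, at 24 h (green) and 10 days (purple), with black bars for group means. Spry4 lies above the controls with FGF9 at both times, by 2.89 and 2.48 on the log2 scale, and Smad6 with BMP4, by 3.34 at 24 h and 0.99 at 10 days.

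At 24 h, the changes made by FGF9 and FGF2 overlapped most. For this pair, 9421 probe sets changed alike in direction and 1 oppositely, where independent lists would share 1000 higher and 1005 lower (covariance 0.156, r = 0.96). For FGF9 and FGF1, 5876 changed alike and 81 oppositely, where independent lists would share 668 higher and 578 lower (covariance 0.0831, r = 0.83). The slope of FGF1 on FGF9 was 0.53. For FGF1 and FGF2, 5955 changed alike and 91 oppositely, where independent lists would share 717 higher and 622 lower (covariance 0.085, r = 0.82). For FGF9 and BMP4, 932 changed alike and 592 oppositely, where independent lists would share 181 higher and 188 lower (covariance 0.0107, r = 0.15). At 10 days, for FGF9 and FGF2, 6893 probe sets changed alike in direction and 606 oppositely, where independent lists would share 1096 higher and 1029 lower (covariance 0.1, r = 0.62), with a slope of FGF2 on FGF9 of 0.41. For FGF9 and FGF1, 783 changed alike and 302 oppositely, where independent lists would share 221 higher and 110 lower (covariance 0.0164, r = 0.22). For FGF1 and FGF2, 1209 changed alike and 47 oppositely, where independent lists would share 141 higher and 105 lower (covariance 0.0293, r = 0.58). For FGF9 and BMP4, 1069 changed alike and 926 oppositely, where independent lists would share 336 higher and 251 lower (covariance 0.0158, r = 0.17). No number under independence was computed for opposite calls, so the excess of alike calls cannot show a shared direction for FGF9 and BMP4.

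All these comparisons used the same 3 control arrays of their time. Unchanged groups simulated against shared controls gave a covariance of 0.0051, r = 0.49 and at most 0 shared calls in 100 simulations. Each observed covariance lay above the simulated one. The simulated r and calls come from groups without change, so observed ones cannot be judged by them. Part of the excess in shared calls can come from the shared controls, which at 3 arrays are too few to split into parts of 2 or more. Covariances and r are of log2 differences, and genes are not independent replicates in them.

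Direct tests between the FGFs at 24 h separated FGF1 from the others. FGF9 gave higher Hbegf (log2 difference 3.28 ± 0.13), a ligand of the EGF receptor (probe set 10803947, log2 signal 11.79 ± 0.034 SD against 8.516 ± 0.064 SD), Clcf1 (3.10 ± 0.098), Il11 (2.93 ± 0.14), Plau (2.89 ± 0.095) and Cd93 (2.69 ± 0.15) than FGF1. Lower were Nt5c1a (-1.99 ± 0.099), Nuak2 (-1.96 ± 0.11), Spata18 (-1.86 ± 0.15), Krt19 (-1.80 ± 0.18) and Bbox1 (-1.77 ± 0.18). Of the FGF and ERK response genes, 16 of 19 were higher and 2 lower (17 and 2 adjusted over the list alone, median 0.78, camera adjusted p = 1.3e-15) with FGF9, among them Spry4 (2.21 ± 0.085), Phlda1 (2.53 ± 0.088) and Dusp6 (1.67 ± 0.082). Astrocyte genes had Aqp4 (-0.61 ± 0.043), and 0 of 16 were higher and 14 lower (0 and 14 adjusted over the list alone, median -0.23, camera adjusted p = 2e-08, adjusted p = 0.052 with an estimated correlation). In all, 5259 probe sets passed in limma, 2566 higher with FGF9 and 2693 lower, of which 373 and 480 by 1.5-fold or more, and of the 9 lists called only the FGF and ERK response list held with an estimated correlation.

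FGF2 against FGF1 at 24 h gave higher Il11 (log2 difference 3.63 ± 0.14) (probe set 10703953, log2 signal 9.616 ± 0.18 SD against 5.988 ± 0.026 SD), Lif (3.62 ± 0.18), Hbegf (3.49 ± 0.13), Clcf1 (3.33 ± 0.098) and Cd93 (3.28 ± 0.15). Lower were Nuak2 (-1.79 ± 0.11), Cyp2j3 (-1.77 ± 0.11), Gdpd2 (-1.65 ± 0.098), C9h2orf72 (-1.64 ± 0.064) and Pik3ip1 (-1.55 ± 0.076). Protease genes differed, and 11 of 20 were higher and 4 lower (11 and 4 adjusted over the list alone, median 0.51, camera adjusted p = 1.8e-05) with FGF2, among them Plau (3.22 ± 0.095) and Mmp3 (2.49 ± 0.13), stromelysin. Of the oligodendrocyte progenitor genes, 0 of 13 were higher and 11 lower (0 and 11 adjusted over the list alone, median -0.43, camera adjusted p = 2.3e-08). Among them are Gpr17 (-1.37 ± 0.09) and Pdgfra (-0.64 ± 0.058). In all, 6320 probe sets passed in limma, 2920 higher with FGF2 and 3400 lower, of which 460 and 520 by 1.5-fold or more, and of the 8 lists called the oligodendrocyte progenitor, astrocyte, FGF and ERK response and protease lists held with an estimated correlation.

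FGF9 and FGF2 differed in few probe sets at 24 h. Lower with FGF9 were Mmp3 (log2 difference -2.59 ± 0.13) (probe set 10907881, log2 signal 6.479 ± 0.29 SD against 9.074 ± 0.18 SD), Serpinb2 (-2.35 ± 0.22), an inhibitor of plasminogen activators, Mmp13 (-2.12 ± 0.091), Kl (-1.32 ± 0.12), klotho, and Ptges (-1.22 ± 0.11), a prostaglandin synthase. Higher were Sectm1b (0.76 ± 0.12), Tmem255b (0.72 ± 0.11), Gja5 (0.69 ± 0.13), a connexin (not passing without FGF9 replicate 2 or FGF2 replicate 1, limma adjusted p = 0.096 and 0.054), Cspg4 (0.60 ± 0.082) and Fn3k (0.59 ± 0.072). For the protease list, 1 of 20 were higher and 5 lower (3 and 10 adjusted over the list alone, median -0.19, camera adjusted p = 1.6e-07). For oligodendrocyte progenitor genes, 4 of 13 were higher and 0 lower (8 and 0 adjusted over the list alone, median 0.13, camera adjusted p = 4.6e-10). An example is Pdgfra (0.43 ± 0.058). Cholesterol synthesis genes were lower as a list, and 0 of 20 were higher and 3 lower (0 and 12 adjusted over the list alone, median -0.14, camera adjusted p = 1.6e-11). In all, 169 probe sets passed in limma, 71 higher with FGF9 and 98 lower, of which 7 and 35 by 1.5-fold or more, and of the 10 lists called the oligodendrocyte progenitor, protease, cholesterol synthesis and stress response lists held with an estimated correlation. The count was 15 with only the 6 arrays compared in the fit (3 higher and 12 lower), 359 with array weights, 88 without FGF9 replicate 2 and 101 without FGF2 replicate 2, and with low-signal probe sets left out 102 were higher and 87 lower.

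At 10 days the FGFs differed widely. Against FGF1, FGF9 gave higher Sectm1b (log2 difference 4.57 ± 0.12) (probe set 10749762, log2 signal 11.48 ± 0.18 SD against 6.905 ± 0.12 SD), Inka2 (4.47 ± 0.13), Dio2 (4.46 ± 0.21), Gfral (4.46 ± 0.13) and Mamdc2 (4.40 ± 0.16). Lower were Spata18 (-3.28 ± 0.15), Bbox1 (-3.24 ± 0.18), Krt19 (-3.03 ± 0.18), Hydin (-2.91 ± 0.14) and C3 (-2.77 ± 0.24), a complement component. Of the FGF and ERK genes, 17 of 19 were higher and 0 lower (19 and 0 adjusted over the list alone, median 1.34, camera adjusted p = 7e-12) with FGF9, among them Etv4 (3.22 ± 0.094) and Spry2 (2.34 ± 0.065). Of the neuronal genes, 0 of 23 were higher and 22 lower (0 and 22 adjusted over the list alone, median -1.08, camera adjusted p = 2.5e-16, adjusted p = 0.091 with an estimated correlation). Examples are Scn2a (-1.68 ± 0.076) and Stmn2 (-1.59 ± 0.084). Of the microglial genes, 1 of 19 were higher and 13 lower (1 and 14 adjusted over the list alone, median -0.40, camera adjusted p = 0.0024, adjusted p = 0.45 with an estimated correlation). An example is Csf1r (-0.64 ± 0.086). In all, 12914 probe sets passed in limma, 7300 higher with FGF9 and 5614 lower, of which 1459 and 2283 by 1.5-fold or more, and of the 11 lists called only the FGF and ERK response list held with an estimated correlation.

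Against FGF2 at 10 days, FGF9 gave higher Inka2 (log2 difference 4.39 ± 0.13) (probe set 10818155, log2 signal 11.33 ± 0.11 SD against 6.946 ± 0.19 SD), Sucnr1 (3.84 ± 0.12), Nrarp (3.66 ± 0.15), a Notch target, Mamdc2 (3.38 ± 0.16) and Slco1c1 (3.13 ± 0.15), a thyroid hormone transporter. Lower were Cyp4b1 (-4.49 ± 0.18), Ptx3 (-4.04 ± 0.098), Spata18 (-2.87 ± 0.15), S100a6 (-2.71 ± 0.17) and Fmo5 (-2.63 ± 0.12). Of the cell cycle genes, 20 of 21 were higher and 1 lower (20 and 1 adjusted over the list alone, median 1.71, camera adjusted p = 8.1e-13, adjusted p = 0.12 with an estimated correlation). Members include Rrm2 (2.51 ± 0.13) and Top2a (2.21 ± 0.13). Of the FGF and ERK response genes, 14 of 19 were higher and 2 lower (14 and 2 adjusted over the list alone, median 1.03, camera adjusted p = 4.3e-09). These include Etv4 (2.85 ± 0.094) and Spry4 (2.12 ± 0.085). Astrocyte genes showed Fgfr3 (1.11 ± 0.052), and 11 of 16 were higher and 0 lower (12 and 0 adjusted over the list alone, median 0.40, camera adjusted p = 2.5e-06, adjusted p = 0.12 with an estimated correlation). Neuronal genes were lower than with FGF2, and 0 of 23 were higher and 21 lower (0 and 21 adjusted over the list alone, median -0.63, camera adjusted p = 1.4e-12, adjusted p = 0.12 with an estimated correlation). In the myelin genes, Mbp (-0.071 ± 0.08) and Mog (0.013 ± 0.085) did not pass. In all, 9983 probe sets passed in limma, 5508 higher with FGF9 and 4475 lower, of which 993 and 1572 by 1.5-fold or more, and of the 9 lists called only the FGF and ERK response list held with an estimated correlation.

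FGF2 against FGF1 at 10 days gave higher Sectm1b (log2 difference 4.2 ± 0.12) (probe set 10749762, log2 signal 11.1 ± 0.15 SD against 6.905 ± 0.12 SD), Cyp4b1 (3.51 ± 0.18), Dio2 (3.29 ± 0.21), Ptx3 (3.15 ± 0.098) and H19 (2.93 ± 0.68). Lower were Kcnj13 (-1.72 ± 0.13), a potassium channel, Ermn (-1.69 ± 0.098), Usp18 (-1.64 ± 0.28), Dlx5 (-1.62 ± 0.12) and Prokr2 (-1.62 ± 0.11). Of the reactive astrocyte genes, 19 of 24 were higher and 0 lower (21 and 0 adjusted over the list alone, median 0.68, camera adjusted p = 2.4e-12, adjusted p = 0.077 with an estimated correlation). Among them are Socs3 (2.50 ± 0.09) and Timp1 (1.3 ± 0.063). Of the myelin genes, 4 of 26 were higher and 15 lower (4 and 15 adjusted over the list alone, median -0.30, camera adjusted p = 0.00041, adjusted p = 0.3 with an estimated correlation). Examples are Mog (-0.99 ± 0.085) and Mobp (-1.06 ± 0.1). In all, 8286 probe sets passed in limma, 3947 higher with FGF2 and 4339 lower, of which 598 and 648 by 1.5-fold or more. None of the 10 lists called by camera held with an estimated correlation.

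Whether a factor acted alike at both times was tested as an interaction, the difference from controls at 10 days minus that at 24 h. For FGF9, the value was highest for Dio2 (log2 4.97 ± 0.3), Slco1c1 (4.26 ± 0.21), Anpep (4.05 ± 0.3), Pygm (3.99 ± 0.24), muscle glycogen phosphorylase, and Sucnr1 (3.73 ± 0.17), and lowest for Cd93 (-3.39 ± 0.21), Clcf1 (-3.29 ± 0.14), Lrrc15 (-3.24 ± 0.14), Il11 (-3.11 ± 0.19) and Ccl7 (-2.97 ± 0.18). Astrocyte genes shifted upwards relative to controls. Of these, 15 of 16 were higher and 0 lower (15 and 0 adjusted over the list alone, median 1.04, camera adjusted p = 1.2e-13), with Aldh1l1 (1.53 ± 0.066) and Fgfr3 (1.67 ± 0.073). Oligodendrocyte progenitor genes did so as well, and 12 of 13 were higher and 0 lower (12 and 0 adjusted over the list alone, median 0.80, camera adjusted p = 2.5e-07). An example is Gpr17 (2.04 ± 0.13). Neuronal genes shifted downwards, and 0 of 23 were higher and 21 lower (0 and 22 adjusted over the list alone, median -1.02, camera adjusted p = 1.7e-13, adjusted p = 0.1 with an estimated correlation). An example is Nefh (-2.27 ± 0.19). In all, 9278 probe sets passed in limma, 4269 with a positive interaction and 5009 with a negative one, of which 1702 and 1952 by 1.5-fold or more. The oligodendrocyte progenitor, astrocyte and stress response lists held with an estimated correlation, the last not without low-signal genes (adjusted p = 0.12).

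For FGF1, the interaction was highest for Aox1 (log2 2.44 ± 0.15), Akr1c19 (2.29 ± 0.19), Lcat (2.20 ± 0.11), Mal (2.13 ± 0.17) and C3 (2.01 ± 0.34), and lowest for Spon2 (-3.39 ± 0.17), Lrrc15 (-3.10 ± 0.14), Socs3 (-2.61 ± 0.13), Ccl7 (-2.38 ± 0.18) and Tbxas1 (-2.37 ± 0.13). FGF and ERK response genes were lower in the interaction. Of these, 0 of 19 were higher and 13 lower (0 and 15 adjusted over the list alone, median -0.64, camera adjusted p = 2e-14). Members include Ccnd1 (-1.72 ± 0.1), Etv5 (-1.43 ± 0.11) and Spry4 (-0.82 ± 0.12). Stress response genes also moved down, and 1 of 14 were higher and 12 lower (1 and 12 adjusted over the list alone, median -0.33, camera adjusted p = 2.6e-06). In all, 4370 probe sets passed in limma, 1857 with a positive interaction and 2513 with a negative one, of which 658 and 577 by 1.5-fold or more. The astrocyte, FGF and ERK response, BMP and SMAD target and stress response lists held with an estimated correlation.

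For FGF2, the interaction was highest for Moxd1 (log2 4.04 ± 0.26), Aox1 (3.68 ± 0.15), H19 (3.58 ± 0.96), Dio2 (3.57 ± 0.3) and Cyp4b1 (3.57 ± 0.25), and lowest for Cd93 (-4.34 ± 0.21), Ccl7 (-3.76 ± 0.18), Il11 (-3.51 ± 0.19), Clcf1 (-3.39 ± 0.14) and Lif (-3.38 ± 0.26). The FGF and ERK genes had 1 of 19 higher and 17 lower (1 and 17 adjusted over the list alone, median -1.37, camera adjusted p = 7.4e-12). These include Spry4 (-2.73 ± 0.12) and Dusp6 (-1.46 ± 0.12). Cell cycle genes were lower too, and 1 of 21 were higher and 19 lower (1 and 19 adjusted over the list alone, median -0.82, camera adjusted p = 1.5e-06, adjusted p = 0.32 with an estimated correlation). An example is Mcm5 (-2.06 ± 0.2). Astrocyte genes were higher, and 12 of 16 were higher and 0 lower (12 and 0 adjusted over the list alone, median 0.63, camera adjusted p = 5.3e-09). In all, 8880 probe sets passed in limma, 3992 with a positive interaction and 4888 with a negative one, of which 1870 and 1329 by 1.5-fold or more. The astrocyte and FGF and ERK response lists held with an estimated correlation.

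For BMP4, the interaction was highest for the replication and division genes Pclaf (log2 2.70 ± 0.27), Rrm2 (2.63 ± 0.19), Ect2 (2.42 ± 0.2), Top2a (2.42 ± 0.19) and Ndc80 (2.33 ± 0.25), and lowest for Nog (-2.73 ± 0.082), Slc7a3 (-2.59 ± 0.21), Smad6 (-2.35 ± 0.13), Casp4 (-2.13 ± 0.24) and Atf5 (-2.13 ± 0.19). Of the cell cycle genes, 21 of 21 were higher and 0 lower (21 and 0 adjusted over the list alone, median 1.59, camera adjusted p = 2.4e-41). Of the myelin genes, 2 of 26 were higher and 17 lower (2 and 20 adjusted over the list alone, median -0.64, camera adjusted p = 5.9e-20). Among them are Mag (-1.5 ± 0.12) and Mbp (-0.93 ± 0.11). BMP and SMAD targets had 2 of 17 higher and 10 lower (2 and 10 adjusted over the list alone, median -0.52, camera adjusted p = 4.8e-09). Examples are Smad7 (-1.61 ± 0.14) and Id1 (-0.73 ± 0.15). In all, 1833 probe sets passed in limma, 861 with a positive interaction and 972 with a negative one, of which 338 and 239 by 1.5-fold or more. The myelin, BMP and SMAD target, cell cycle and stress response lists held with an estimated correlation.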

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

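The interaction tests and the other splits of the arrays were set before their results were seen, and only the account of what the largest splits have in common was made afterwards. Each factor's effect differed between 24 h and 10 days by the test of the difference itself, in 9278 probe sets for FGF9, 4370 for FGF1, 8880 for FGF2 and 1833 for BMP4. In 6 instances a list was called by camera in opposite directions at the 2 times with the preset correlation. In every one of them the call at 24 h, at 10 days or at both was lost with an estimated correlation, so a reversal was not established at both times. Values follow in the order 24 h, 10 days and difference. With FGF9, astrocyte genes (medians -0.63, 0.35 and 1.04, camera adjusted p = 1.2e-13 for the difference, adjusted p = 0.014, 0.21 and 0.012 with an estimated correlation) and microglial genes (medians -0.24, 0.37 and 0.637, camera adjusted p = 0.00028 for the difference, adjusted p = 0.51, 0.48 and 0.46 with an estimated correlation) were called lower, then higher. With FGF1, FGF and ERK response genes were called higher, then lower (medians 0.65, -0.18 and -0.638, camera adjusted p = 2e-14 for the difference, adjusted p = 0.009, 0.31 and 0.002 with an estimated correlation). At 10 days 2 of these 19 rose and 2 fell, and the list mean of 2 of 3 arrays lay beyond the controls. BMP and SMAD targets (medians -0.22, 0.12 and 0.327, camera adjusted p = 5e-05 for the difference, adjusted p = 0.22, 0.019 and 0.022 with an estimated correlation) and interferon-stimulated genes (medians -0.40, 0.14 and 0.546, camera adjusted p = 0.00022 for the difference, adjusted p = 0.56, 0.51 and 0.5 with an estimated correlation) were called lower, then higher. For the latter, 0 of 17 members passed in limma at 10 days (3 higher at unadjusted p under 0.05), and 0 of 3 arrays lay beyond the controls. With BMP4, cell cycle genes were called lower, then higher (medians -0.40, 1.19 and 1.59, camera adjusted p = 2.4e-41 for the difference, adjusted p = 0.22, 0.0054 and 0.003 with an estimated correlation).

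In 100 splits of the 12 arrays of each interaction, the real one included, 1 gave as many changed probe sets as the real split for FGF9 (highest other 9056), 3 for FGF1 (5839), 2 for FGF2 (12207) and 2 for BMP4 (3176). As splits mix treated and control arrays, they give no chance level here. The largest other split of FGF1, FGF2 and BMP4 each exchanged all 3 treated arrays with all 3 controls at one time and kept the other time, so that the contrast became the sum of both effects. For FGF1 a further split, of 4524, exchanged 3 treated arrays at 24 h and 1 at 10 days, and the highest of FGF9 exchanged 2 at 24 h.

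For the comparisons of 3 arrays with 3, there are 10 splits, which cannot give a share under 0.05; the real split was the 1 of 10 with as many calls each time. At 24 h, the real count and the highest of the other splits were 10439 and 0 for FGF9, 6974 and 88 for FGF1, 11223 and 0 for FGF2, and 2066 and 2 for BMP4. At 10 days they were 12696 and 0 for FGF9, 1485 and 0 for FGF1, 9873 and 1 for FGF2, and 2694 and 0 for BMP4, and for the controls over time 5138 and 0. Between FGFs they were 5259 and 56 (FGF9 and FGF1), 169 and 0 (FGF9 and FGF2) and 6320 and 1 (FGF2 and FGF1) at 24 h, and 12914 and 1, 9983 and 59, and 8286 and 0 in the same order at 10 days.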

How the results depend on the processing

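The tests of only probe sets with 1 symbol and of a further quantile normalization for lists and named genes were chosen after seeing the data. Of the 19 counts of changed probe sets, most stayed within 1.5 times under every alternative. With only the arrays compared in the fit, which leaves fewer arrays to estimate the spread, the counts were 1321 (BMP4, 24 h), 938 (FGF1, 10 days), 1319 (BMP4, 10 days) and 15 (FGF9 against FGF2, 24 h, 3 higher and 12 lower), and array weights gave 359 for the last, whose cause was not tested. With fewer probe sets tested, those of 1 symbol, the counts were 8195 for FGF9 against controls and 8289 for FGF9 against FGF1, both at 10 days. Leaving out 1 array gave 853 to 1333 for FGF1 at 10 days (853 without control replicate 3, 943 and 889 without FGF1 replicates 2 and 3) and 88 to 145 for FGF9 against FGF2 at 24 h (88 without FGF9 replicate 2 and 101 without FGF2 replicate 2). With low-signal probe sets left out, that comparison had 102 higher and 87 lower. Of 361 list tests, 186 were called with the preset correlation and 50 of these with an estimated one, none in the other direction; fry called 238, the fit without low-signal genes 163 (27 of the 186 lost and 4 gained) and a further quantile normalization 184. That normalization ended 5 calls, astrocyte genes over time in controls (adjusted p = 0.11), interferon-stimulated genes in FGF9 against FGF2 at 10 days (0.095), and myelin, mesenchymal and BMP and SMAD genes in the FGF2 interaction (0.056 each). With 1.5-fold or more required in both factors, shared calls fell, by construction, to 944 (FGF9 and FGF1), 2260 (FGF9 and FGF2), 958 (FGF1 and FGF2) and 96 (FGF9 and BMP4) at 24 h and to 72, 1284, 219 and 187 at 10 days. Of 421 named genes by comparison, 420 kept direction and side of the threshold under a further quantile normalization and all did under array weights and the block. Of 2850 refits without 1 array, 14 lost the call, 1 gained it and 0 turned direction (limma). Low signal over background limits the array values, and the cause of the other shifts was not tested.

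The replicate numbers do not pair the samples. Deviations from group means correlated with a median r of 0.011 for arrays of the same number (135 pairs) and -0.0092 for other numbers (270 pairs), from -0.26 to 0.24 and from -0.25 to 0.29 respectively. Every array correlated best with its own number in FGF9 against FGF1 at 24 h and FGF9 against FGF2 at 10 days, a hint from the data and not from the design. With the replicate number as a block, the count was 10409 for FGF9 at 24 h, 2620 for BMP4 at 10 days and 159 for FGF9 against FGF2 at 24 h, the block called 187 lists, and in none of the 19 comparisons did the count move by over 1.5 times.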

Other observations

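The lists of motile cilium and amino acid response genes, their tests, the genes named from them and the test of equal lowering of neuronal genes were chosen after the results had been seen. Genes of motile cilia, the beating cilia of ependymal cells, fell at 24 h with every FGF and stayed low with FGF9. The list of 40 axoneme and multiciliated cell genes leaves out the cilium genes seen first among the lowest. At 24 h, 38 of 40 were lower with FGF9 (median log2 -1.10), 38 with FGF2 (-1.06), 31 with FGF1 (-0.57) and 13 with BMP4 (-0.29), with camera p = 0.017, 0.022, 0.037 and 0.064 at an estimated correlation. At 10 days, 35 of 40 were lower with FGF9 (-1.44), 18 with FGF2 (-0.19) and 6 with BMP4 (-0.13), with p = 0.021, 0.49 and 0.25 at an estimated correlation. With FGF1 1 was higher by limma (0.018, p = 0.86 at an estimated correlation). With FGF9 Foxj1 (log2 change -1.05 ± 0.079), the master regulator of motile cilia, and Ccdc39 (-1.03 ± 0.099), an axoneme protein, fell at 24 h, and their log2 changes at 10 days were -1.13 ± 0.079 and -1.61 ± 0.099. The changes of FGF1 and FGF2 differed between the times, with medians of the interaction of 0.57 (27 of 40 higher, p = 0.041 with an estimated correlation) and 0.89 (33 of 40, p = 0.049).

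Genes induced by amino acid shortage, among them tRNA synthetases, amino acid transporters and enzymes of serine synthesis, were lower at 10 days with FGF1, FGF2 and BMP4 in most members. Of 39 such genes, none of them in the stress response list and 1 of them (Mthfd2) seen before among the lowest with FGF1, 31 fell with FGF1 (median log2 -0.43, p = 3.3e-06 with an estimated correlation), 30 with FGF2 (-0.40, p = 0.0095) and 33 with BMP4 (-0.49, p = 5.5e-06). With FGF9, 25 fell and 8 rose (-0.30, p = 0.075 with an estimated correlation). Examples are Shmt2 (FGF1 log2 change -0.66 ± 0.06), mitochondrial serine hydroxymethyltransferase, and Slc7a11 (BMP4 log2 change -1.19 ± 0.1), the cystine transporter. In untreated cultures 30 of the 39 rose from 24 h to 10 days (p = 0.00068 with an estimated correlation), with Slc7a11 (0.73 ± 0.1) and Slc7a5 (0.35 ± 0.041).

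For this amino acid pattern, a single raised control array is argued against, since without any 1 of the 3 control arrays at least 95.9% of the list median remained for FGF1, FGF2 and BMP4. A rise in the 10-day controls that the treated cultures did not share goes with part of it, since the list median of these controls lay 0.315 above the 24 h controls, with FGF1, FGF2, BMP4 and FGF9 at -0.11, -0.065, -0.15 and 0.02 at 10 days. Yet these treated cultures lay at 0.068, 0.25, 0.064 and 0.23 at 24 h, so their own levels were lower at 10 days than at 24 h, which a missed rise alone leaves unexplained. The biological difference between the treatments stays open, and medium use by the cultures was not measured here.

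Neuronal genes fell with FGF9 at 10 days by a median of 1.14 on the log2 scale. A further quantile normalization left the median at -1.18, but cannot test the arrays' shifted low end, as 22 of 23 genes had high signal. A smaller share of neuronal RNA that lowers every neuronal gene alike cannot be told apart from changes that differ between genes. The SD of the changes over the 23 genes (0.58) was 8.11 times their median standard error (0.072), but probe sets that respond unequally at low and high signal would spread an equal loss as well. That unequal response stays open too, as Spearman's rho of control level and size of change across genes, which are not independent replicates, was -0.23 (permutation p = 0.3, bootstrap interval -0.74 to 0.3). Fewer neurons or lower expression per neuron may each remain, as neither was measured here.

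For the cilium genes among the lowest with FGF9 at 10 days, a loss of the class as a whole was in keeping with the list of other cilium genes, whose median was -1.44 (camera with an estimated correlation, p = 0.021). That median was -1.41 after a further quantile normalization, too slight to test the shifted low end. Whether multiciliated cells were fewer or each made less of these transcripts may differ between the factors and was not tested here.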
